A study of Schizosaccharomyces pombe with 127 samples.

How the data were processed

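The deposited table holds linear ratios of the 2 dyes of each array, Cy5 (strain RNA) over Cy3 (wild-type pool), with the dyes given per the labels. The scaling and background correction that the authors applied are not given in the sources used here. Array medians of the deposited ratio lay between 0.932 and 1.09, so the values had been centred near 1, and the array titles name GenePix result files per the labels. The table has 9858 probes on 127 arrays, 2 probes per gene, and 6 values of exactly 0, which were set to missing before taking log2; the lowest other ratio was 0.018. Signal over background is not given, so no depth can be stated per array. The 2 probes of a gene correlated across genes with a median of 0.62 per array at 0 min (lowest 0.37) and 0.84 at 60 min (lowest 0.78).

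The direction follows the dyes in the labels. At 0 min 9 pairs of arrays correlated below -0.3 over all probes, the lowest at -0.42, while no pair of 60 min arrays correlated below 0.65. At 0 min a strain is close to the pool, so deviations of different strains could oppose each other. The direction was kept, and the deleted gene was checked in every strain with a probe for it (62 of 63 at 0 min).

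Probes were named through the platform annotation and then through the gene table of assembly ASM294v3, by gene identifier. Of all probes 9632 carried 1 symbol, 44 several and 182 none. The 4929 features comprise 4816 named genes, 4791 of them in the current table, and 113 unnamed features, which are given by probe identifier. No coordinates are given, as the build behind the probes is not stated. Of the listed symbols 3 of the nitrogen list and 4 of the ribosome biogenesis list had no match. The names prk1 and skp1 belong to more than 1 gene; the kinase was taken, since the label says kinase deletion. The strain labelled skp1 is called gsk3 here, that labelled prk1 srb10, and that labelled spm1 pmk1. Strains labelled by a shortened locus name are called by the gene of that locus, such as atg1 for CC63_08C, vps15 for BC119_07, gad8 for CC24B10_07, ssp2 for CC74_03C, ppk22 for BC1861_09 and cdk11 for BC18H10_15.

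Groups came from the array titles. The 60 min wild-type array is titled wild type, though another field calls it a kinase deletion, and it was grouped by its title. The 0 min and 60 min arrays of one strain share its genotype and were paired by strain name. The series text names 68 kinase deletions and 5 others; 63 deletion strains were analysed here. One strain, hal4, has the 0 min array only and enters no paired test, and ppk18 has no single-gene probe for its deleted gene.

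From the ratios were computed log2 values, centred on the array median, and the mean of the probes of a gene. A gene needed a value in at least 80% of the pairs. R 4.3.3 with limma 3.58.1 (lmFit, eBayes) fitted the change per gene and the pathway comparisons, with Benjamini-Hochberg adjustment over genes, and camera tested 17 lists with an inter-gene correlation preset at 0.01, beside an estimated one. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 ran the exact permutation tests of list means (adjusted over 54 tests, 18 lists by 3 outcomes, for each comparison) and the permutations with 100000 resamples. The deleted gene of a strain was left out of its list means and of its correlation, but not of its count of signature genes. The fits were tested on simulated data with the real spread per gene. With 62 strains 98% of genes changed by 0.25 were called. With 3 strains against the others 90% of genes changed by 1 and 32% of those changed by 0.5 were called, and with 2 strains 70% and 24%. Beside 50 changed genes at each of 4 sizes, the false calls numbered 17 with 62 strains, 4 with 3 strains and 7 with 2, so some of the few pathway calls can be false. The simulation covered the change alone, its genes varied independently, and no simulated strain stood apart. Random trios of the real strains gave up to 397 genes for the change and 555 for the mean, so false calls can be more numerous than simulated.

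Gene lists, tests and the rule for named genes were fixed before the data were examined. For starvation the rule took the 10 largest rises and falls among genes with adjusted p under 0.05 and one direction in at least 90% of strains, and the 3 members of each list that changed most. For the pathway fits it took up to 8 genes per direction and 3 of the tied list; for the single strains 3 of the tied lists; for signature genes 5 strains with 5 genes each; for response size the 5 lowest, the 5 highest and the pathway strains; and for deleted genes the 5 lowest strains and those not below the others. Strains named for a deleted gene that was the lowest at 0 min only or at neither time, the genes of pathway fits called under an alternative alone, and the levels of pap1 and atf1 in other arrays, were chosen after their values were seen. Alternatives covered centring, quantile normalization, probe level, thresholds, pairing, the array series, the non-kinase deletions and each pathway strain left out. Others, chosen after seeing the data, left out arrays with doubted labels. No array was moved to another group on the basis of its values.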

Results

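The series measured messenger RNA in fission yeast (Schizosaccharomyces pombe) strains that each lack 1 gene, most of them a protein kinase gene. Each strain was grown in minimal medium with nitrogen (0 min) and then starved of nitrogen for 60 min. Labelled RNA of a strain (Cy5) was hybridised on a 2-colour array against a pool of wild-type RNA (Cy3) that served as common reference, so each value is a ratio of the strain to that pool. The arrays analysed here comprise 63 deletion strains at 0 min, 62 at 60 min and 1 wild-type array at each time; 62 strains have both times. Each strain has 1 array per time. The strain is therefore the unit of the limma fits and of the permutation tests, whose p-values measure the spread between strains. The camera tests instead set the genes of a list against the other genes. Their p-values depend on the correlation assumed between genes, which was preset or estimated. The number of arrays limits the precision, and values for a single strain have no replicate. All values below are log2 ratios after centring each array on its median, and a spread is the SD over strains unless stated.

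The first question was whether each array carries the deletion its label names. The deleted gene lay on average 1.89 below the mean of the other strains at 0 min (SD 1.14, n = 62) and 1.79 below it at 60 min (SD 1.18, n = 61), a mean of -1.83 over both times. It was the lowest of all deletion arrays in 52 of 62 strains at 0 min and in 47 of 61 at 60 min, where chance would give about 0.984. The permutation p was 1e-05 at both times, the smallest that 100000 resamples can give (two-sided). The lowest values, averaged over both times, were those of rst2, a zinc-finger transcription factor (-4.59), ssp2, the catalytic subunit of AMP-activated kinase (-3.91), cyr1, adenylate cyclase (-3.89), ppk25 (-3.39) and gad8, a kinase downstream of TOR complex 2 (-3.19). A deleted gene leaves background signal alone, so the size of these values depends on the background and on the level of the pool at each probe, and their order does not rank the deletions. In 8 strains it was the lowest at neither time: chk1, the DNA damage checkpoint kinase (0.03, the only mean not below the others), ppk38 (-0.02), mug27 (-0.07), spo4 (-0.09), wis1, the MAPK kinase of the stress pathway (-0.10), hri1 (-0.16), mde3 (-0.19) and srk1 (-0.20). A probe outside the deleted part would not show the deletion, so such a value does not by itself put a label in doubt.

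In 6 strains the deleted gene was the lowest of all deletion arrays at 0 min but not at 60 min. For atf1, the transcription factor of the stress pathway, it was -4.21 at 0 min and -0.22 at 60 min. For byr1, the MAPK kinase of the pheromone pathway, the values were -2.89 and -0.18. For ppk22 they were -3.72 and -0.53, for cdk11 -1.95 and -0.10, for ppk33 -0.83 and -0.33, and for srb10, labelled prk1, -0.64 and -0.37. For ppk15 and cmk2 the deleted gene was the lowest at 60 min only. The values at 0 and 60 min were -1.20 and -2.78 in ppk15, and -0.22 and -0.90 in cmk2. The cmk2 value at 0 min lay within the SD of the others (0.23), so its probes do not clear the label of that array. In wis1 the deleted gene stood at 0.06 and -0.27. The 60 min array labelled byr1 held atf1 at -3.79, with 0.79 in the next lowest 60 min array. The 60 min array labelled atf1 held pap1, a transcription factor of the oxidative stress response, at -4.61, with 0.23 in the next lowest. These 2 arrays are therefore called the arrays labelled byr1 and atf1, and directions drawn from them carry that doubt. For ppk22 and cdk11 the same probes showed the deletion at 0 min, so the labels of their 60 min arrays are in doubt as well. For ppk33 and srb10 the 0 min values were smaller, yet beyond the SD of the others (0.32 and 0.22). At 60 min the deleted gene ranked 11 from the lowest in ppk33 and 4 in srb10, so the labels of these 60 min arrays are not cleared. The deviations of the 2 srb10 arrays from the other strains correlated across genes at 0.30, and those of ppk33 at 0.0049.

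**Figure D1:**
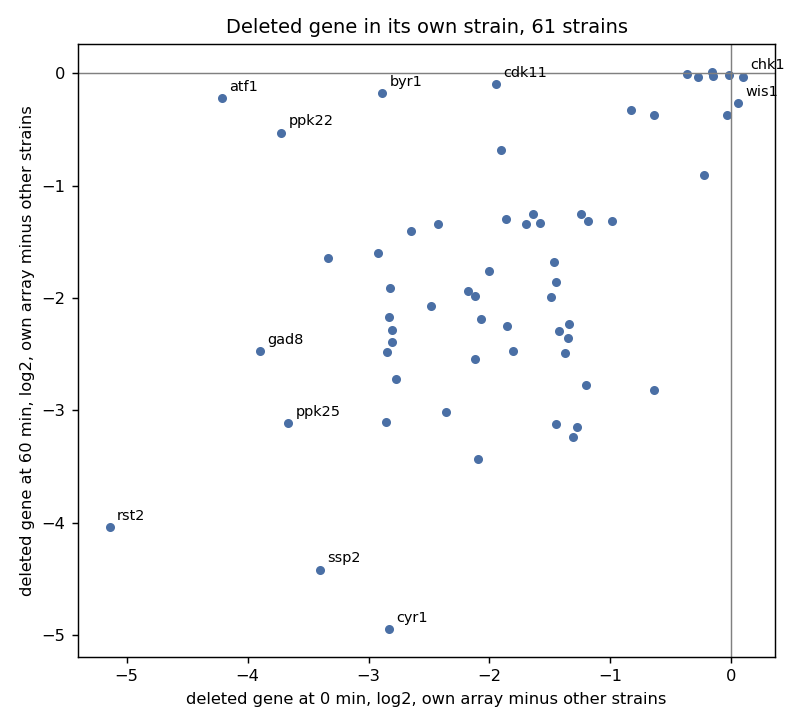
Level of the deleted gene in its own array minus the mean of the other deletion strains, at 0 min (horizontal axis) and at 60 min (vertical axis), both on the log2 scale; each point is 1 of 61 strains. Most points lie below 0 on both axes, while atf1, byr1, ppk22 and cdk11 lie low at 0 min and close to 0 at 60 min.

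Nitrogen starvation changed many genes in the 62 strains. Genes for the use of uracil, purines and other nitrogen sources led the rise: urg1 rose by 6.07 (SD 0.77, n = 62), urg2 by 5.97, xan1, a xanthine dioxygenase, by 5.47, uro1 by 4.99 and dal2, of the allantoin pathway, by 4.41. The vacuolar protease gene isp6 rose by 4.58 (SD 0.54), pbi2 by 4.32, SPBC800.11 by 4.45, SPAC1399.01c by 4.37 and SPAC1039.02 by 4.30. Genes of ribosomal proteins led the fall: rpl35A01 changed by -3.88 (SD 0.52), rpp101 by -3.78, rps2201 by -3.77, rpl2702 by -3.65, rpl44 by -3.54, rps2202 by -3.53 and rpl3002 by -3.48. The gene ser3 of serine synthesis changed by -3.63 (SD 0.70), and 2 unnamed features, probe:pJ5566_100079 and probe:c977_101134, by -3.74 and -3.49. By limma with the strain as block and Benjamini-Hochberg adjustment, 803 of 4929 genes had an adjusted p under 0.05 and at least a 2-fold change, 371 higher and 432 lower; 304 and 391 of those moved the same way in every strain. Quantile normalization, which gives all arrays one distribution, reduced the count to 478 (175 higher and 303 lower), and the wider spread of the 60 min arrays (mean SD over probes 0.98, against 0.36 at 0 min) is then removed.

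Protein synthesis genes fell together. Of 123 ribosomal protein genes 122 fell, with a median of -2.76, and rpl3703 alone rose (0.86). All 56 measured ribosome biogenesis genes fell (median -1.14), led by gar1 (-2.59), gar2 (-2.36) and rlp7 (-2.17), of which the first 2 encode nucleolar proteins. Of 10 chaperone genes 9 fell (median -1.58), among them hsp90 (-2.31), ssa2 (-2.08) and the mitochondrial ssc1 (-1.87), and psi1 rose (0.65). Of 30 amino acid synthesis genes 25 fell and 5 rose (median -0.47), with lys4 at -2.83, ilv5 at -2.37 and lys12 at -1.98. These 4 lists had camera adjusted p of 9.46e-45, 4.26e-17, 7.32e-04 and 1.09e-05. With an estimated correlation the adjusted p were 0.183, 0.183, 0.261 and 0.256, so none of the 4 calls held.

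Genes for recycling and uptake rose. All 28 autophagy genes rose (median 0.88), led by isp6, psp3 (2.48), another protease gene, and atg4 (1.92). Of 20 nitrogen uptake and use genes 15 rose and 3 fell (median 1.37): dal51 rose by 3.94, the amino acid permease gene isp5 by 3.84 and the oligopeptide transporter gene isp4 by 3.54. Of 20 stress response genes 18 rose and 1 fell (median 1.52), among them the metallothionein gene zym1 (3.19), ish1 (3.19) and cta3 (2.48). Of 23 respiration genes 21 rose and 1 fell (median 0.54), with idh1 at 1.18, mdh1 at 1.12 and idh2 at 1.10, of the citric acid cycle. The camera adjusted p of these 4 lists were 3.99e-09, 0.00181, 9.46e-05 and 2.85e-04; with quantile normalization the respiration call was lost (0.313). With an estimated correlation the adjusted p were 0.204, 0.261, 0.256 and 0.306.

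Genes of the cell cycle were higher at 60 min. All 9 core histone genes rose (median 1.65), with htb1 at 2.03, hhf2 at 1.74 and hta2 at 1.71. Of 13 targets of the MBF factor, which drives S phase genes, 10 rose and 1 fell (median 0.79): cdc18 by 1.32, cdc22 by 1.26 and cdt2 by 1.11. Of 17 septation genes 14 rose and 1 fell (median 0.37), with adg3 at 1.95, sid2 at 1.33 and spo12 at 0.96. Of 18 proteasome genes 15 rose and 1 fell (median 0.24), with rpn2 at 0.48, rpt5 at 0.48 and rpt6 at 0.42. The camera adjusted p were 2.10e-04, 0.00157, 0.0125 and 0.0426, and with quantile normalization the core histone (0.119) and proteasome (0.313) calls were lost. With an estimated correlation the adjusted p of the 4 lists were 0.261, 0.204, 0.361 and 0.407.

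The mating and meiosis genes moved little at 60 min. Of 22 mating and pheromone genes 14 rose and 5 fell (median 0.20, camera adjusted p = 0.239), with ste7 at 1.57, mam3 at 1.20 and mam4 at -0.86. The early meiosis list had 6 risen and 1 fallen of 14 genes (median 0.08, adjusted p = 0.474), with dmc1 at 1.22, moa1 at -0.83 and hop1 at 0.63 (1.26 and -0.01 by its 2 probes, so the probes disagree). The middle meiosis and spore list had 6 risen and 2 fallen of 12 (median 0.09, adjusted p = 0.534), with spo3 at 0.66, bgs2 at 0.59 and mde10 at -0.31. All 6 carbon derepression genes rose (median 0.67, adjusted p = 0.0664), led by fbp1 (0.95), ght3 (0.87) and mal1 (0.85). Of 9 iron uptake genes 6 fell and 3 rose (median -0.74, adjusted p = 0.252), with str1 at -2.62, frp1 at -1.58 and fio1 at -1.22. The phosphate list had 1 measured gene, tgp1, which rose by 2.33, and no list test. Adjusted over the list alone, the counts of these lists were the same except for MBF targets, where 11 rose.

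**Figure D2:**
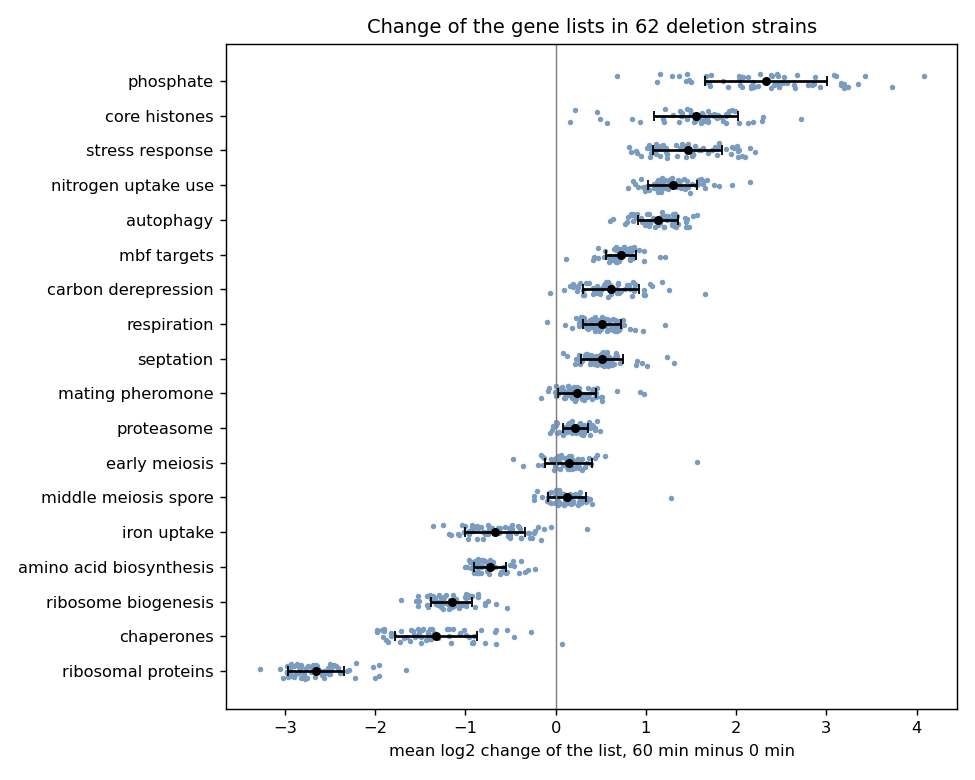
Mean log2 change (60 min minus 0 min) of each fixed gene list; each blue point is 1 of 62 deletion strains, and black symbols give the mean and SD over strains. Ribosomal protein genes lie lowest, with a median gene at -2.76, and the phosphate list is a single gene.

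The wild-type pair responded with a size close to the mean of the deletion strains. Its response, as the slope on the mean change of the deletion strains over 802 genes, was 1.02, rank 35 from the lowest. Its ribosomal protein list changed by -2.78, against -2.65 in the deletion strains (SD 0.31), and its autophagy list by 1.06 against 1.13 (SD 0.22). Its proteasome list changed by -0.34, lower than in every deletion strain (mean 0.22, SD 0.14). Its early meiosis list rose by 0.69 against 0.14 (SD 0.26) and its middle meiosis and spore list by 0.47 against 0.13 (SD 0.21), each rank 62 of 63, and the phosphate gene by 3.51 against 2.33 (SD 0.67), rank 61. The label of the 60 min wild-type array is in doubt, since its title says wild type and another field a kinase deletion. The arrays of this pair carry numbers far apart in the array series, while in 51 of 62 strains they are at most 1 apart, so its change holds time together with the series. No test of the pair was run.

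A strain's deviation from the others was partly shared between its 2 arrays. The correlation across genes between the deviations at 0 and 60 min averaged 0.31 over 62 strains (SD 0.21), against -0.00425 between different strains. It was above 0 in 59 strains, and the permutation p was 1e-05, the smallest possible with 100000 shuffled pairings (two-sided). Genes are not independent replicates within such a correlation. On average 7.79 genes per strain (SD 18.6) lay at least 2-fold from the mean in the same direction at both times, against 1.22 with shuffled pairings (permutation p = 1e-05). The median was 3 genes per strain, and 7 strains had 0. The deleted gene was kept in these counts, and in strains such as ppk1 and cdr2 it was the only gene counted. Part of the excess over shuffled pairings therefore follows from the deletion itself. The mean rests in part on the cyr1 strain: without atf1, cyr1, cgs1 and rst2 it was 4.64.

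The strains with the most such genes were those of the cyclic AMP pathway, and gsk3 and vps15. For cyr1, rst2 and cgs1 the array numbers are close to each other and apart from most others. Their counts therefore hold the array series together with the genotype. The cyr1 strain had 139, 75 higher and 64 lower: mug14 deviated by 6.02 (mean of both times), fbp1, of gluconeogenesis, by 5.30, ght3, a hexose transporter, by 4.72, mfm1, a pheromone precursor, by 4.55 and SPAC1039.02 by -4.78. The rst2 strain had 39, with rst2 itself at -4.52, SPAC27D7.11c at -2.46, mfm2 at -2.32, ste11, the main regulator of mating genes, at -2.24 and isp4 at -2.13. The cgs1 strain had 28, with mfm2 at -2.84, isp4 at -2.46, cgs1 itself at -2.25, ste11 at -2.23 and SPCC794.04c at -1.96. In the gsk3 strain, labelled skp1, all 26 were lower: probe:pB15E9_100603 by -3.82, mdm12 by -3.59, SPAC3H1.06c by -3.37, the pheromone protease gene sxa2 by -3.29 and fhn1 by -2.71. These 5 varied widely, with an SD over the other strains of 0.86 to 1.33 at the 2 times. The level of probe:pB15E9_100603 was lowest in mde3 at 0 min (-5.83) and in dsk1 at 60 min (-4.91), not in gsk3. The vps15 strain had 22, with SPCC737.04 at 2.23, SPBC19C7.04c at 2.17, isp4 at -2.10, probe:pB15E9_100203 at 2.05 and SPAC27D7.11c at 2.02.

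The size of the starvation response was described per strain. The slope of a strain's change on the mean change of the others over 802 genes had an SD of 0.11 around 1.00. It was lowest in ppk22 (0.66), cyr1 (0.66), chk1 (0.82), cdk11 (0.83) and vps15 (0.83), and highest in mde3 (1.21), ppk3 (1.17), ppk13 (1.15), ppk27 (1.15) and ppk25 (1.12). Among the pathway strains it was 1.05 in wis1, 1.05 in wis4, 1.11 in the pair labelled atf1, 0.90 in the pair labelled byr1, 1.05 in spk1, 0.88 in ssp1 and 0.99 in ssp2. Further values were 1.01 in cgs1, 1.02 in rst2 and 1.00 in gad8. The slopes of ppk22 and cdk11 rest on 60 min arrays with doubted labels. No test was run on single slopes.

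The cyr1 and cgs1 strains, with opposite lesions of the cyclic AMP pathway, lay on opposite sides of the other strains in mating gene levels. Cyr1 makes cyclic AMP, and Cgs1 is the regulatory subunit that restrains protein kinase A. The mean of the mating and pheromone list was higher in cyr1 than in cgs1 by 1.46 at 0 min and by 2.31 at 60 min (exact permutation p = 0.00317 and 0.000529 over all ordered pairs of 62 strains, two-sided, the second the smallest possible; adjusted p = 0.0762 and 0.0286 over 54 tests). Each side of this comparison is 1 array per time, so the p says how far apart these arrays lie among pairs of strains and is no test of a replicated genotype. In the cyr1 strain at 60 min mfm1 deviated by 5.67, mfm3 by 5.21 and mam2 by 4.53; in cgs1 mfm2 deviated by -2.89, ste11 by -1.67 and mfm1 by -1.99. The carbon derepression list was higher in cyr1 than in cgs1 by 2.89 at 0 min and by 2.49 at 60 min (exact p = 0.0270 and 0.0116, adjusted p = 0.0907 and 0.0762), and with quantile normalization by 2.11 and 1.50. The cyr1 strain led this difference, with fbp1 at 5.75, ght3 at 5.42 and ght4 at 3.36 at 0 min, while cgs1 ranked 51 of 62 at 0 min, with ght3 at -0.09, fbp1 at 0.29 and mal1 at 0.46. The rst2 strain ranked lowest in the carbon list at 0 min (-0.93, SD of the others 0.45) and lowest in the mating list (-1.18, SD 0.24), with ste11 at -3.40, mfm1 at -2.96 and mfm2 at -2.32, and ght3 at -1.67, inv1 at -1.37 and fbp1 at -1.05. At 60 min rst2 stood closer to the others, at -0.35 in the carbon list (SD 0.40, rank 4 of 62) and -0.48 in the mating list (SD 0.30, rank 2), and its changes were among the highest (0.57, rank 60, and 0.71, rank 61). The rst2 array at 0 min had the widest spread of the 0 min arrays (SD over probes 0.82, against a mean of 0.36). Its 0 min values and its changes can therefore follow in part from the spread of that array. For cyr1 minus cgs1 the change of the carbon list was -0.39 (exact p = 0.351), and -0.61 with quantile normalization (exact p = 0.268). The arrays of these 3 strains carry numbers close to each other and apart from most others, so values set against the other strains hold the array series together with the genotype, while cyr1 minus cgs1 lies within one series.

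**Figure D3:**
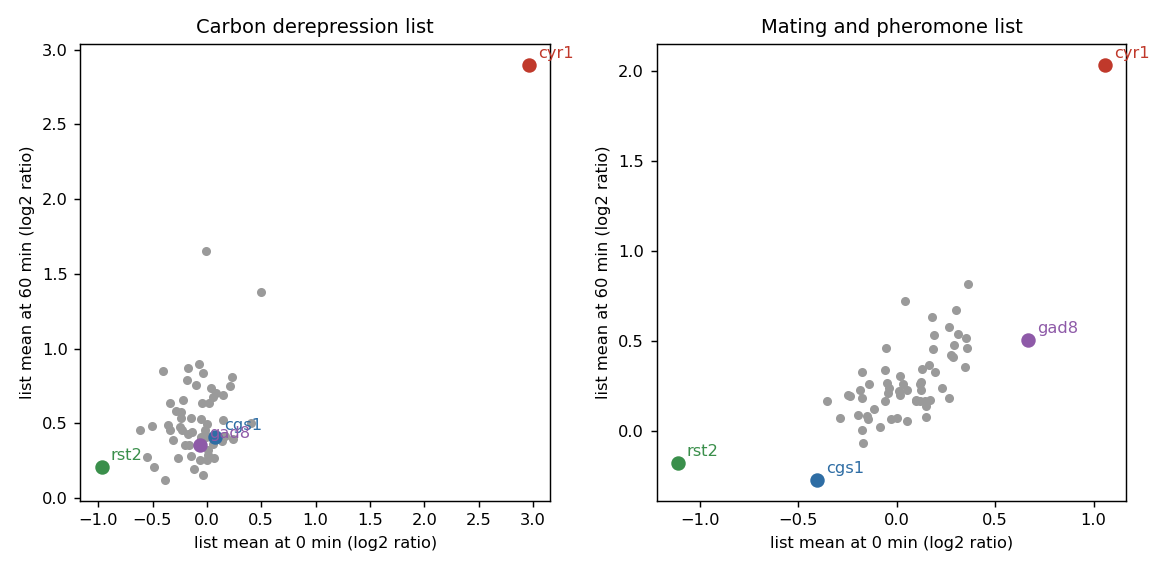
Mean log2 ratio of the carbon derepression list (left) and of the mating and pheromone list (right) in each of 62 deletion strains, at 0 min (horizontal axis) and 60 min (vertical axis). The cyr1 strain has the highest value in both lists at both times, and rst2 the lowest at 0 min.

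In the gad8 strain the mating and pheromone list stood 0.62 above the other strains at 0 min, rank 61 of 62 (exact permutation p = 0.0484, adjusted p = 0.554), and 0.22 above them at 60 min (exact p = 0.323). Its change was the lowest of all strains, at -0.41 (exact p = 0.0645, where 1 strain against 61 cannot go below 0.0161). At 0 min mfm1 deviated by 1.94, ste11 by 1.35 and sxa2 by 1.21.

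In the main setting few genes differed between the stress MAPK strains wis1, wis4 and atf1 and the others. This count depends on its members: wis1 did not show its deletion, and the 60 min array labelled atf1 is in doubt. With the 0 min arrays alone, more genes were called without wis1 than with it. By limma on the mean of both times 2 genes were lower in the 3 strains: hsp9, a heat shock gene (-2.17, SE 0.44, adjusted p = 0.0246), and pdi4 (-0.55, SE 0.12, adjusted p = 0.0284). At 0 min hsp9 deviated by -5.12 in wis4 and by -5.52 in atf1, but by -0.34 in wis1; at 60 min the values were -2.21 in wis4, -0.06 in the array labelled atf1 and 0.23 in wis1, whose own gene was not low either. The 60 min array labelled byr1, which lacks atf1 signal, held hsp9 at -4.46, with 0.33 in the next lowest, so whether atf1 shares the low level at 60 min depends on the doubted labels. The gene pdi4 lay below the others in each strain at both times (-0.90 to -0.31). With quantile normalization the 2 genes called were others, both higher: SPCC1494.08c (0.70, adjusted p = 0.00248) and agp3 (0.78, adjusted p = 0.0316), while hsp9 (-1.75, SE 0.45) and pdi4 (-0.63, SE 0.14) stayed lower and did not pass (adjusted p = 0.145 and 0.0591). Of the stress list, gpx1, a glutathione peroxidase (-0.93, adjusted p = 0.647), and rds1 (-0.71, adjusted p = 0.928) did not pass. With the 0 min arrays alone, free of the doubted 60 min labels, 5 genes were called: hsp9 (-3.66, SE 0.49, adjusted p = 1.50e-06), gpx1 (-1.77, SE 0.31, adjusted p = 5.16e-04), grx1 (-1.14, SE 0.19, adjusted p = 3.29e-04), SPCC1494.08c (0.66, SE 0.12, adjusted p = 7.83e-04) and agp3 (0.57, SE 0.12, adjusted p = 0.0194). In that limma fit pdi4 did not pass (-0.48, SE 0.15, adjusted p = 0.477). At 0 min gpx1 deviated by -3.79 in atf1, -1.29 in wis4 and -0.25 in wis1. The stress list mean of the 3 strains differed by -0.41 at 0 min (exact permutation p = 0.0186, adjusted p = 0.908) and by -0.24 at 60 min (exact p = 0.232). Neither passed after adjustment over 54 tests. Without the pairs labelled atf1 and byr1 5 genes were called; without the atf1 strain alone there were 0, with hsp9 at -1.86 (SE 0.53) and pdi4 at -0.64 (SE 0.14).

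The change between the times differed in 5 genes: hsp9 by 2.98, pap1 by -1.91, plb1, a phospholipase, by -1.13, scr1, a repressor of sugar-regulated genes, by -0.78 and sec5, of the exocyst, by -0.59 (adjusted p 0.0384, 0.0174, 0.0368, 0.0376 and 0.0174). The pap1 difference lies in the 60 min array labelled atf1, where it deviated by -5.41, against -0.05 in wis1 and 0.31 in wis4. In that array gst2, a glutathione transferase of the stress list, deviated by -5.34 (difference -1.13, adjusted p = 0.532), and gpx1 by 0.10 (difference 1.70, adjusted p = 0.237). Without the pairs labelled atf1 and byr1 0 genes were called. The pap1 difference was then -0.02 (SE 0.23, before 0.39) and that of hsp9 1.62 (SE 0.52, before 0.67). By contrast sec5 stood at -0.64 (SE 0.15, before 0.12), plb1 at -0.92 (SE 0.29, before 0.25) and scr1 at -0.52 (SE 0.21, before 0.17), so most of their fold stayed, and for sec5 the call ended with the larger SE of 2 strains. All 5 genes were chosen in a fit that already held wis1 and wis4, so a similar fold there was in part built in. For the change, 535 genes had an unadjusted limma p under 0.05, where chance gives about 246. Genes are not independent and the fit holds the array labelled atf1, so this excess is no test. The change of the stress list differed by 0.17 (exact permutation p = 0.476).

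The pheromone MAPK strains byr1 and spk1 differed little from the others in the mating list: by -0.02 at 0 min, 0.01 at 60 min and 0.03 in the change (exact permutation p = 0.873, 0.964 and 0.819). Their stress list differed by -0.46 at 0 min (-0.49 in byr1 and -0.42 in spk1) and by -0.61 at 60 min (-1.15 in the array labelled byr1 and -0.08 in spk1). Neither passed over 54 tests (exact permutation p = 0.0328 and 0.0180, adjusted p = 0.253 for each), and the 60 min value rests mainly on the array labelled byr1. By limma on the mean of both times, atf1 (-1.80), gpd1, of glycerol synthesis (-1.29), and SPAC26F1.07 (-1.10) were lower (adjusted p = 0.01, 0.0398 and 0.0398), and sxa2 (0.71), ste7 (-0.37) and mei2 (-0.30) did not pass (adjusted p = 0.947). At 60 min atf1 deviated by -5.46 in the array labelled byr1 and by 0.05 in spk1. The change differed in SPAC922.04 (-1.99, adjusted p = 0.00915) and rpc11, a subunit of RNA polymerase (-0.79, adjusted p = 0.0280), while sxa2 (0.69), rgs1 (0.55) and sxa1 (-0.39) did not pass. An unadjusted limma p under 0.05 was reached by 375 genes for the change, where chance gives about 246, and this fit holds the array labelled byr1. Without the byr1 pair 0 genes were called: the change of SPAC922.04 was then -0.38 (SE 0.46, before 0.38), while that of rpc11 was -0.66 (SE 0.23, before 0.17), near its value with both strains; for the mean, atf1 was -0.31 (SE 0.41, before 0.34), gpd1 -0.62 (SE 0.38, before 0.28) and SPAC26F1.07 -0.46 (SE 0.32, before 0.24). With the 0 min arrays alone for the mean, 0 genes were called, with atf1 at -0.89 (SE 0.49), gpd1 at -0.84 (SE 0.38) and SPAC26F1.07 at -0.81 (SE 0.30).

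The AMPK strains ssp1 and ssp2 differed from the others by limma in 3 genes of the mean, of which 2 were the deleted genes: ssp2 (-2.01, adjusted p = 3.08e-07) and ssp1 (-0.96, adjusted p = 0.0117). The third, SPBC1289.14, was higher by 1.29 (adjusted p = 0.0118), with 3.13 in ssp2 and 0.34 in ssp1 at 0 min. The mating genes mfm3 (-0.69), mfm2 (-0.62) and mfm1 (-0.55) did not pass (adjusted p = 1.00 for each). For the change, 0 genes passed by limma, and 259 had an unadjusted p under 0.05, where chance gives about 246; mei2 (0.63), mfm2 (0.56) and sxa2 (-0.48) did not pass. The mating list differed by -0.17 at 0 min, -0.06 at 60 min and 0.10 in the change (exact permutation p = 0.321, 0.709 and 0.458).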

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

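All tests of the labels in this part were chosen after the result was seen; the counts over other splits were planned. The change from 0 to 60 min differed between the stress MAPK strains and the others in 5 genes, and between the pheromone MAPK strains and the others in 2 genes. Both were picked out because the response differed between groups of strains by a test of the difference itself. For the stress strains, 12 of 100 trios of strains, the real one included, gave at least 5 genes, and the highest other trio gave 397, so chance cannot be excluded. For the mean of both times, 37 of 100 trios gave at least the real 2 genes, and the highest other gave 555. The trio with 555 genes held cyr1 and rst2. The trio with 397 held ppk22 and cdk11, whose 60 min arrays have labels in doubt, since the deleted gene stood at -0.53 and -0.10 there against -3.72 and -1.95 at 0 min. For the change from 0 to 60 min over all strains, 1 of 100 random exchanges of the times within strains, the real one, gave as many genes (802 over genes with no missing value, against 79 in the highest other). A change that the strains share cancels in such exchanges, so this count adds little to the paired fit.

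Part of both pathway counts lies in the 60 min arrays labelled byr1 and atf1. Without these pairs the difference of pap1 was -0.02 against -1.91 with them, and without the byr1 pair that of SPAC922.04 was -0.38 against -1.99. By contrast sec5 (-0.64 against -0.59), plb1 (-0.92 against -1.13) and rpc11 (-0.66 against -0.79) kept most of their fold. They were chosen in fits that already held the remaining strains, so a similar fold was in part built in and is no support for the calls. An exchange of these 2 arrays with each other is argued against by byr1, which stood 0.0253 from the mean of the others in the array labelled atf1, rank 32. RNA of an atf1 deletion under the byr1 label is a candidate explanation: atf1 lay 4.58 below the next lowest array, and among the 0 min arrays the one labelled atf1 correlated best with it (0.48, next 0.31, its own label 0.28). RNA of a pap1 deletion under the atf1 label is another: pap1 lay at least 4.70 below the next lowest array with each of its probes. No biological explanation was tested, and neither hypothesis was used to move an array.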

How the results depend on the processing

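Settings that left out doubted labels (the pairs labelled atf1 and byr1, strains whose deleted gene was not lowest in its own array, the 60 min arrays, or wis1) were chosen after seeing the data; the others were planned. The count of genes changed by starvation lay between 798 and 837 without centring, with genes free of 0 ratios, within the main array series, without the non-kinase deletions, with the wild-type pair, with medians over strains, and without doubted strains. With no replicate block, as an unpaired fit, it was 803, and 11 lists were called. It was 478 with quantile normalization, 1714 at probe level, where each gene counts by its 2 probes, 1616 from 1.5-fold and 4308 with no minimum change; the last 3 follow from their construction. Lists called numbered 12, 9 to 12 under the other settings and 0 with an estimated correlation. Quantile normalization lost core histones, proteasome and respiration, and each setting with 11 lost the proteasome list. The deleted gene (-1.91 to -1.73), the same-strain correlation (0.29 to 0.34) and the wild-type slope (1.01 to 1.10) kept their direction under all settings run for them. Signature genes averaged 4.59 with array numbers under 1500, 4.64 without atf1, cyr1, cgs1 and rst2, 21.4 at probe level and 44.7 from 1.5-fold, each above its shuffled pairings. The SD of the response over strains was 0.0168 as a Pearson correlation, another scale.

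The pathway counts are small and moved with most settings; the cause was not tested. With quantile normalization the 2 genes of the stress mean were both higher (in the main setting both lower) and not the same genes, and the change differed in 11 genes for the stress MAPK, 12 for the pheromone MAPK and 9 for the AMPK strains, and the AMPK mean in 13. Of the genes named in the report, pap1 and plb1 were among the 11, while sec5, scr1 and hsp9 were not (adjusted p = 0.249, 0.237 and 0.104); neither SPAC922.04 nor rpc11 was among the 12 (0.144 and 0.155), and gpd1 left the pheromone mean (0.182). With array numbers under 1500 the stress change gave 9, the pheromone mean 12 and change 5, and the AMPK mean 5 and change 4. Without atf1, cyr1, cgs1 and rst2 where not tested, the stress mean gave 4, the pheromone mean 15 and change 8, and the AMPK mean 5 and change 3. With values as deposited the pheromone change gave 1, and at probe level the pheromone mean gave 5 and the change 4. With other strains that exclude the remaining pathways, the stress mean gave 6, the pheromone mean 20 and change 9, and the AMPK mean 5 and change 1. Leave-one-out over the strains of a pathway gave 0 (without atf1) to 3 (without wis1) for the stress mean, 0 (without atf1) to 11 (without wis1) for the stress change, 0 (without byr1) to 24 (without spk1) for the pheromone mean, 0 to 48 for its change, and 0 to 3 for the AMPK change; a lone strain is taken to vary like the others. Without the pairs labelled atf1 and byr1 the stress mean gave 5 and the change 0. With the 0 min arrays alone the stress mean gave 5, and 21 without wis1, and the pheromone mean 0.

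List tests here are set by their unadjusted exact p against 0.05; over 54 tests none of those in this paragraph passes in the main setting. The stress list at 0 min was -0.44 with quantile normalization (exact permutation p = 0.118), -0.35 without the pairs labelled atf1 and byr1 (0.0932), and -0.59 (without wis1) to -0.31 (without wis4) in leave-one-out (exact p = 0.00874 and 0.133, and 0.105 without atf1). The mating list of the pheromone strains turned sign without byr1, to 0.0660 at 0 min, -0.0308 at 60 min and -0.0969 for the change, none past the threshold; without spk1 the values were -0.115, 0.0468 and 0.162. The change of the mating list in the AMPK strains was 0.41 with quantile normalization (exact p = 0.0487). In gad8 the mating list at 0 min was 0.78 with quantile normalization and 0.62 without the atf1 and byr1 pairs, with exact p of 0.0645 and 0.05, and its change was -0.39 within the main array series and -0.38 without the non-kinase deletions, with exact p of 0.0357 and 0.0345, from 1 array per time. Of the named genes, hop1 gave -0.00637 with one of its probes (1.26 with the other), rds1 0.0255, and gst2 0.98 without the atf1 and byr1 pairs, each with its sign turned. In leave-one-out gst2 ran from -2.23 (without wis4) to 0.95 (without atf1), mfm2 from -1.34 (without ssp2) to 0.0930 (without ssp1) and sxa2 from -1.27 (without ssp1) to 0.32 (without ssp2). Of the other values of named genes under planned settings, 824 stayed on their side of the threshold, 54 fell below it and 2 came to pass it. Genes present in at least 50% of pairs are the same genes as in the main setting, so that setting was not run. Array number could not be restricted for cyr1, cgs1, rst2 and the wild type. Signal over background is not given, so its limit cannot be stated per value; the agreement of probe pairs was lower at 0 min than at 60 min.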

Other observations

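The tests of amino acid genes in this part were chosen after the result was seen; that of arrays with close numbers was written before. The atg1 and vps15 strains lack a kinase that starts autophagy and the regulatory subunit of a phosphatidylinositol 3-kinase. At 60 min ser3 stood 2.76 and 2.95 above the other strains in them (SD of the others 0.50), lys1 1.28 and 1.08 (SD 0.28), and inv1, invertase, 4.11 and 2.47 (SD 0.52). The allantoin gene dal2 stood at -2.12 and -3.33 (SD 0.94). At 0 min their respiration list was higher by 0.45 (exact permutation p = 0.000529, adjusted p = 0.00952), their stress list by 0.66 (adjusted p = 0.0238), and their nitrogen list lower, by -0.49 (adjusted p = 0.0357; -0.23 in atg1 and -0.74 in vps15). Their change was higher in the nitrogen list by 0.63 (adjusted p = 0.0238), in the carbon list by 0.68 (adjusted p = 0.0357) and in the amino acid list by 0.48 (adjusted p = 0.00952), and lower in the respiration list, by -0.49 (adjusted p = 0.0238).

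The amino acid synthesis list was higher in both strains at 60 min, by 0.70 in atg1 and 0.57 in vps15 (SD of the others 0.15; exact permutation p = 0.000529, the smallest possible; adjusted p = 0.00952 over 54 tests). A weaker response in general is argued against for atg1 by its slope of 0.99, rank 25 of 62. For vps15 it stays open: its slope of 0.83, rank 5, lies below the mean minus 1 SD (0.89), its ribosomal protein list at 60 min stood 0.96 above the others (SD 0.27; -0.03 in atg1), and the change of its amino acid list went beyond what the slope predicts by 1.995 SD of the other strains, where more than 2 was set as the bound against it. Both strains were picked from their values, so each p here is too small by an unknown amount, and no biological explanation was tested.

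The shared deviation of a strain's 2 arrays might come from arrays hybridised close together, since the 2 arrays of most strains have adjacent numbers. Arrays of different strains with numbers at most 1 apart (43 pairs) correlated on average by 0.0269 (SD 0.20), against 0.31 for the same strain, which argues against array order as its cause. Differences in culture that both arrays of a strain share stay open.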
